A study of Mus musculus with 24 samples.

How the data were processed

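Liver RNA was sequenced from 24 mice in 8 groups of 3. The mice lacked either Shp2, the phosphatase encoded by Ptpn11, or the lipid phosphatase Pten in hepatocytes. The sample labels name the liver carcinogen diethylnitrosamine (DEN) for the Shp2 mice and not for the Pten mice, though the protocol text can be read as DEN for both. In each model, mice received poly I:C, a synthetic double-stranded RNA, at 15 µg per kg of body weight into the abdomen, or did not, and livers were collected after 1 week (7 days) or 2 weeks (14 days). Per the labels' protocols, RNA was extracted with Trizol and libraries were made with an Illumina TruSeq kit from total RNA.

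The deposited data were 4 tables, each setting a poly I:C group against its control group, with 46073 genes in each. Per the submitters' processing notes, the authors used Bowtie 0.12.2, Cuffdiff and the mouse build mm9. The authors deposited 1 FPKM value (fragments scaled by transcript length and library size) for each group and gene, not for each mouse. The authors also deposited a test score, a p-value and a q-value (a p-value adjusted for many tests), per the file headers. The fold column was not used, since some of its cells hold spreadsheet text. Log2 fold changes were computed as log2 of the poly I:C value over the control value, and they differed by over 0.01 from the deposited column for at most 3 tested genes in a table. How many reads lie behind each value is not given in the sources used here, so no counting interval was computed. The tables carry no coordinates, and none are printed because the reference in hand is of another build. Of the gene identifiers, 98.0% were found in that reference. A further 272 entries repeat a symbol, and 27 symbols read as dates and were not named. Where a symbol had several rows, the tested row with the higher level was used.

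A gene counted as changed where its status was OK and the authors' deposited q was below 0.05, which matched the deposited column of calls for every tested gene. No test of mouse against mouse was possible, since the tables used here hold only group values, and no value here has a standard deviation or an n of its own. The lowest deposited p-value was 5e-05 in every table. An error of a fold change was derived as the log2 fold change divided by the normal quantile of its deposited p-value. At the lowest p-value this error is an upper bound, 24.7% of the log2 fold change. The quantile was 1.75 times the deposited test score at the median gene of the first table and much the same in the other 3, so the score was not fold change over error on a normal scale. The planned source of the error could therefore not be used, and the p-value took its place, a choice made after seeing the data. No p of the difference is printed, since the normal scale is approximate with 3 mice in a group. The q-values belonging to a p-value were equal (within 1e-05) in both tables of a model for every shared p-value and differed between models. The authors' adjustment was thus shared by both tables of a model. Adjusting within a table alone gave fewer calls than the deposited q in every table, so the adjustment did not cover these tests alone. Which other tests it covered is not given in the sources used here.

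Differences of the poly I:C effect between times and between models were tested per gene as the difference of log2 fold changes over the root of the summed squared errors, 2-sided, with Benjamini-Hochberg adjustment below 0.05. Data were simulated with normal noise of the size of these derived errors. In each comparison 100 genes were given a true difference of 1 on the log2 scale and another 100 a difference of 3. Of the 100 genes differing by 3, this test recovered 43% between times in Shp2 livers (13679 genes run in all). It recovered 62% between times in Pten livers (15194 genes run), 44% between models at 1 week (13607 genes run) and 53% at 2 weeks (13655 genes run). For a difference of 1 it recovered 8%, 13%, 4% and 6%. Of its calls in a single simulated run for each comparison, 5.56%, 1.32%, 7.69% and 3.28% were false, in the same order. Few genes were called in each run, so differences between these shares are not read. The noise was drawn from the errors that the test assumes, so these shares lay near the threshold by construction. They do not show how many calls are false in the real data. With these numbers of changed genes the test thus missed most differences of 1. Its recovery where more genes differ was not simulated.

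The tests of single comparisons, 41 gene lists of 5 to 38 members, the first alternatives and the rule for naming genes were fixed before the data were examined. Some lists share members, such as Cxcl9 in the interferon-gamma-induced and classical macrophage lists, so results of different lists are not independent. For each list the members called over all genes, those called when adjusted over the list alone (Benjamini-Hochberg on the deposited p-values) and the median log2 fold change are given. Each median was also placed among those of 10000 random lists matched on mean expression in 20 bins, as a description only. The genes named are the deleted gene, up to 10 called genes with the largest rise and 10 with the largest fall (1 FPKM or more in the higher group, above 0 in both, leaving out predicted genes, Rik names, LOC entries, microRNAs, snoRNAs and antigen receptor segments), up to 4 called members of each list at 1 FPKM or more (or up to 2 as values where none was called), and 16 genes fixed by name: Cd274, Pdcd1, Cxcl9, Cxcl10, Ccl5, Gzmb, Prf1, Ifng, Isg15, Irf7, Stat1, Ifit1, Afp, Gpc3, Mki67 and Tlr3. A gene named in 1 table could be given in the others. Alternatives covered the q threshold, the size of change, filters on low values, pseudocounts of 0.1 and 1, centring on the median gene and the scope of the adjustment. Further alternatives on the sex of the animals, the adjustment within a table, the other time point, the source of the error and the direction of the Shp2 table of 2 weeks were added after seeing the data. Analyses ran in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.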

Results

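Poly I:C is sensed by double-stranded RNA receptors and was given to mice with Shp2-deficient livers, labelled as DEN-treated, or with Pten-deficient livers. The Pten labels do not name DEN, but the protocol text leaves open whether those mice received it. Whole livers were sequenced in 8 groups of 3 mice, and each comparison below sets a poly I:C group against the untreated group of the same model and time. Values are the authors' group FPKM, and a gene is said to have risen or fallen only where its q in the authors' deposited table was below 0.05. The tables used here hold 1 value per group, so the spread between mice is not shown. Levels from different tables are set side by side as a description only, since whether they were normalized together is not given in the sources used here. Tested genes numbered 14683 and 14868 in Shp2 livers at 1 and 2 weeks, and 16124 and 15774 in Pten livers. Genes whose loci held too many fragments for Cuffdiff's test (25, 9, 39 and 47 in the same order), many of them listed at 0, were left out. The median gene at 1 FPKM or more had log2 fold changes of -0.01, -0.02, -0.04 and 0.00. For each gene list, the members called over all genes are given first. The parentheses hold the numbers up and down when adjusted over the list alone and the median log2 fold change. Of 41 lists, the medians of 30, 29, 23 and 17 lay outside the central 95% of random lists.

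The deleted genes were read first. In the poly I:C comparisons Ptpn11 was at 5.10 and 4.59 FPKM in the control and poly I:C groups of Shp2 livers at 1 week and fell at 2 weeks from 12.5 to 6.81 FPKM (log2 -0.88), with an implied error of 0.25 and q = 0.00435 in the authors' deposited table. In Pten livers Ptpn11 was at 8.54 and 8.07 FPKM at 1 week and 9.41 and 9.09 FPKM at 2 weeks, so the Shp2 control group of 2 weeks was not below them. Pten was at 4.17 and 3.94 FPKM and 5.54 and 4.62 FPKM in Pten livers, against 5.89 and 5.79 FPKM and 11.5 and 15.4 FPKM in Shp2 livers. A gene-level value spans exons outside the deleted part and other liver cells keep the gene, so these values are a weak check of the labels.

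The first question was what poly I:C had changed in Shp2 livers after 1 week. Most tested members of the lists of interferon-gamma-induced genes, MHC class II genes, neutrophil markers and monocyte-derived macrophage markers rose. Falls included 10 of 29 tested drug-metabolising genes and 8 of 24 cholesterol synthesis genes. Ubd, a ubiquitin-like modifier, rose from 1.39 to 50.7 FPKM (log2 5.19), and Cd274, which encodes the checkpoint ligand PD-L1, rose from 0.614 to 2.59 FPKM (log2 2.07). In all, 1233 genes passed in the authors' deposited table, 877 up and 356 down. The poly I:C group differed from its control in sex chromosome transcripts too. Xist, the RNA of the inactive X chromosome, rose from 1.41 to 362 FPKM, and the Y-linked Eif2s3y fell from 26.3 to 0.225 FPKM, while Y-linked Kdm5d was listed at 0 after poly I:C. Sex chromosome composition and treatment thus coincided in this comparison.

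Among interferon-gamma-induced GTPases and chemokines, 15 of 20 tested members rose and none fell (17 and 0 adjusted over the list alone, median log2 1.66). Cxcl9 rose from 1.75 to 8.51 FPKM and Cxcl10, like it a ligand of the chemokine receptor CXCR3 of T cells, from 3.87 to 20.8 FPKM. The guanylate-binding protein gene Gbp2 rose from 2.90 to 17.5 FPKM, and Stat1, the transcription factor shared by interferon pathways, from 11.8 to 34.5 FPKM (log2 1.55). Among the type I interferon-stimulated genes, 6 of 36 tested members rose and none fell (6 and 0 adjusted over the list alone, median log2 0.26). Ifit1 rose from 2.51 to 4.41 FPKM, while Isg15 (35.3 and 32.6 FPKM) and Irf7 (25.8 and 32.3 FPKM) did not pass. In MHC class II presentation, 9 of 10 tested members rose and none fell (10 and 0 adjusted over the list alone, median log2 1.93), including H2-DMb1 from 1.80 to 10.2 FPKM and H2-Aa from 29.2 to 121 FPKM. In MHC class I presentation, 7 of 19 tested members rose and none fell (8 and 0 adjusted over the list alone, median log2 0.71), including the immunoproteasome gene Psmb9 from 54.0 to 193 FPKM.

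Among neutrophil markers, 10 of 13 tested members rose and none fell (13 and 0 adjusted over the list alone, median log2 3.11). The granule genes Mpo (from 0.113 to 3.39 FPKM), Ltf (from 2.14 to 31.5 FPKM) and Camp (from 1.46 to 21.0 FPKM) were among the 10 largest rises. Among the monocyte-derived macrophage markers, 13 of 20 tested members rose and none fell (13 and 0 adjusted over the list alone, median log2 1.47), with Trem2 rising from 0.943 to 4.99 FPKM and Ly6c2 from 0.877 to 4.05 FPKM. Among the Kupffer cell markers, 6 of 15 tested members rose and none fell (9 and 0 adjusted over the list alone, median log2 0.59), including Marco from 47.6 to 158 FPKM. Among T cell markers, 5 of 11 tested members rose and none fell (7 and 0 adjusted over the list alone, median log2 1.27), and among NK cell markers, 3 of 5 tested members rose and none fell (4 and 0 adjusted over the list alone, median log2 1.34). Among the cytotoxic effectors, 4 of 7 tested members rose and none fell (4 and 0 adjusted over the list alone, median log2 1.17), with Ccl5 from 10.1 to 28.4 FPKM and Gzma from 1.45 to 6.10 FPKM, whereas Gzmb (0.912 and 1.66 FPKM) did not pass. Prf1, Ifng and Pdcd1 were below 1 FPKM and not tested in any of the 4 tables. Among sinusoidal endothelial markers, 1 of 18 tested members fell and none rose (0 and 1 adjusted over the list alone, median log2 -0.11). Among the stellate cell and fibrosis genes, 8 of 22 tested members rose and none fell (9 and 1 adjusted over the list alone, median log2 0.62), including the collagen gene Col1a1 from 23.3 to 51.2 FPKM.

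In the hepatocyte programme, acute phase genes that rose included Orm2 (from 11.7 to 147 FPKM), Lcn2 (from 29.1 to 250.5 FPKM) and the serum amyloid gene Saa2 (from 32.5 to 323 FPKM): 9 of 24 tested members rose and 2 fell (9 and 2 adjusted over the list alone, median log2 0.36). Among the xenobiotic metabolism genes, 2 of 29 tested members rose and 10 fell (2 and 14 adjusted over the list alone, median log2 -0.58), with Cyp1a2 falling from 279 to 92.5 FPKM. Among the cholesterol synthesis genes, 8 of 24 tested members fell and none rose (0 and 9 adjusted over the list alone, median log2 -0.56), among them the rate-limiting Hmgcr from 133 to 50.2 FPKM. Among the liver tumour-associated genes, 12 of 25 tested members rose and 1 fell (13 and 1 adjusted over the list alone, median log2 0.63). The fetal liver gene Afp rose from 10.2 to 53.7 FPKM (log2 2.39), and Gpc3, an X-linked gene of liver tumours, from 4.93 to 9.04 FPKM. The largest falls outside the Y chromosome included Rgs16 (from 43.4 to 5.37 FPKM, log2 -3.01), the transcriptional repressor Bcl6 (from 15.5 to 2.69 FPKM), Selenbp2 (from 116 to 19.9 FPKM) and Ces3a (from 182 to 33.0 FPKM). Among growth hormone and sex-dependent liver genes, 3 of 23 tested members rose and 6 fell (4 and 8 adjusted over the list alone, median log2 -0.10). These calls went both ways by sex bias. The male-biased Cyp4a12a rose and the female-biased Cyp2b13 and A1bg fell, while the male-biased Mup3 fell. Of the called genes, 1197 lay outside the X and Y chromosomes, which leaves in sex-dependent genes of other chromosomes. The changes are thus not assigned to poly I:C alone. By the column labels 740 were also called in the same direction at 2 weeks (19 if the direction of that table is turned).

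After 2 weeks in Shp2 livers most tested MHC class II genes, neutrophil markers, monocyte-derived macrophage markers and type I interferon-stimulated genes rose, as did 10 of 24 acute phase genes. Saa2 rose from 12.5 to 1792 FPKM (log2 7.16), Orm2 from 19.4 to 2243 FPKM (log2 6.85) and Saa1 from 37.5 to 2411 FPKM (log2 6.01). Cd274 rose from 0.586 to 5.39 FPKM (log2 3.20) and the MHC class II invariant chain gene Cd74 from 32.4 to 665 FPKM. In all 1853 genes passed in the authors' deposited table, 1349 up and 504 down. Xist stayed at 0.0686 and 0.0141 FPKM and Eif2s3y at 25.8 and 26.2 FPKM in the control and poly I:C groups.

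Among the type I interferon-stimulated genes, 25 of 38 tested members rose and none fell (28 and 0 adjusted over the list alone, median log2 1.12). Irf7, the master regulator of type I interferon, rose from 13.7 to 54.9 FPKM, Ifit1 from 4.46 to 9.60 FPKM and Isg15 from 34.6 to 55.0 FPKM (log2 0.67). Among interferon-gamma-induced GTPases and chemokines, 16 of 21 tested members rose and none fell (17 and 0 adjusted over the list alone, median log2 2.28), with Cxcl10 rising from 6.94 to 67 FPKM, Gbp5 from 0.690 to 6.32 FPKM and the protease inhibitor gene Serpina3g from 4.02 to 40.9 FPKM. Stat1 rose from 17.9 to 68.8 FPKM. Among the double-stranded RNA sensing genes, 2 of 14 tested members rose and none fell (2 and 0 adjusted over the list alone, median log2 0.38). Tlr7, the gene of a receptor for single-stranded RNA, rose from 0.270 to 1.93 FPKM. Tlr3, the endosomal receptor for poly I:C, was at 1.78 and 2.69 FPKM and did not pass. In MHC class II presentation, 8 of 11 tested members rose and none fell (10 and 0 adjusted over the list alone, median log2 3.82), with H2-Aa rising from 15.6 to 288 FPKM. In MHC class I presentation, 9 of 19 tested members rose and none fell (11 and 0 adjusted over the list alone, median log2 1.06).

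Among the monocyte-derived macrophage markers, 17 of 20 tested members rose and none fell (18 and 0 adjusted over the list alone, median log2 3.32). The LPS co-receptor gene Cd14 rose from 0.733 to 28.4 FPKM (log2 5.27), Ms4a4c from 0.404 to 8.02 FPKM and Lyz2 from 14.1 to 192 FPKM. Among the Kupffer cell markers, 12 of 15 tested members rose and none fell (14 and 0 adjusted over the list alone, median log2 1.96), including the resident macrophage gene Adgre1 from 2.52 to 25.6 FPKM. Among classical macrophage genes, 9 of 11 tested members rose and none fell (9 and 0 adjusted over the list alone, median log2 2.28), and among alternative macrophage genes, 4 of 9 tested members rose and 1 fell (6 and 1 adjusted over the list alone, median log2 1.30). Fpr2, a formyl peptide receptor of the first of these lists, rose from 0.559 to 12.4 FPKM, and Mrc1 of the second from 9.17 to 22.5 FPKM. Among neutrophil markers, 14 of 17 tested members rose and none fell (16 and 0 adjusted over the list alone, median log2 3.41), with S100a8 rising from 16.6 to 256 FPKM. In chemokines and cytokines, 13 of 26 tested members rose and none fell (14 and 0 adjusted over the list alone, median log2 2.53). The monocyte attractant Ccl2 rose from 0.568 to 16.4 FPKM, Ccl6 from 5.66 to 62.9 FPKM and Tnf from 0.152 to 1.38 FPKM, while Ccl7 and Ccl12 were listed at 0 in the control group. Among NK cell markers, 6 of 8 tested members rose and none fell (7 and 0 adjusted over the list alone, median log2 2.18), and among T cell markers, 5 of 11 tested members rose and none fell (6 and 0 adjusted over the list alone, median log2 1.45). Cytotoxic effectors followed: 6 of 8 tested members rose and none fell (6 and 0 adjusted over the list alone, median log2 1.68), with Gzmb rising from 1.28 to 2.69 FPKM (log2 1.07) and q = 0.0335 in the authors' deposited table. Among the dendritic cell markers, 6 of 10 tested members rose and none fell (7 and 1 adjusted over the list alone, median log2 1.73), including Batf3 from 1.56 to 15.2 FPKM. Among immune checkpoint genes, 5 of 8 tested members rose and none fell (5 and 0 adjusted over the list alone, median log2 1.41). Among sinusoidal endothelial markers, 1 of 18 tested members rose and none fell (1 and 0 adjusted over the list alone, median log2 -0.08).

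**Figure D1:**
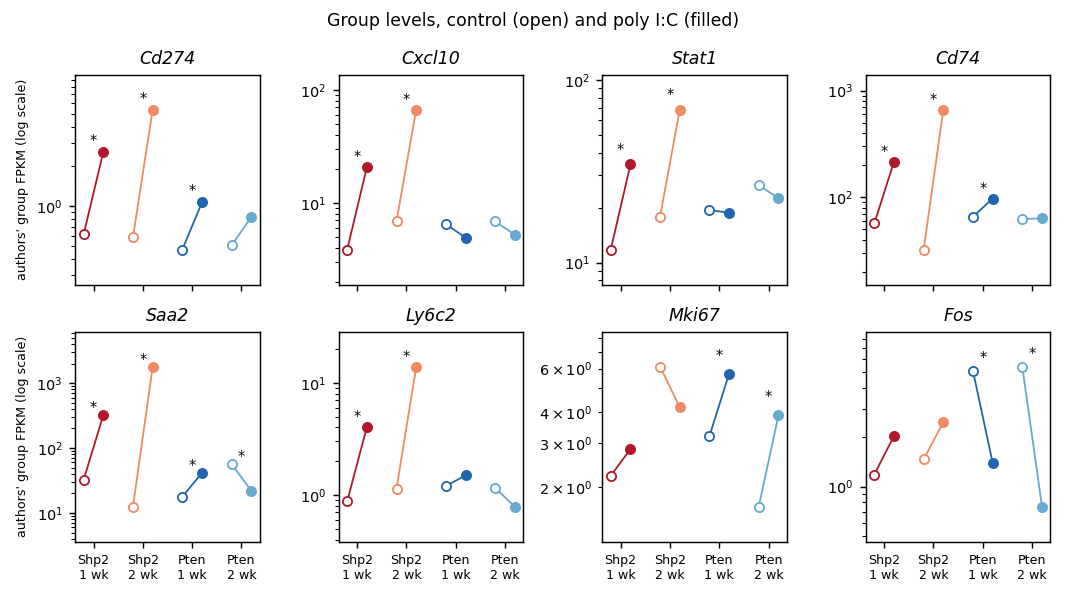
Authors' group FPKM (log scale) of 8 genes in the 4 comparisons, control as open and poly I:C as filled circles, with a star where the authors' deposited q was below 0.05. Each group has 1 value, so no error bars are drawn. Cd274 went from 0.586 to 5.39 FPKM in Shp2 livers at 2 weeks and from 0.507 to 0.830 FPKM in Pten livers at 2 weeks, and Fos fell in Pten livers.

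Among acute phase genes in Shp2 livers at 2 weeks, 10 of 24 tested members rose and 2 fell (10 and 2 adjusted over the list alone, median log2 0.57). The iron hormone gene Hamp rose from 1687 to 4018 FPKM while its copy Hamp2 fell from 1449 to 423 FPKM. These 2 are near-identical, as are the Saa and Orm genes, and how reads were shared among copies is not given in the sources used here. Among the hepatocyte markers, 1 of 23 tested members rose and 5 fell (1 and 7 adjusted over the list alone, median log2 -0.50), including Apoa1 from 12364 to 4557 FPKM and Slc10a1 from 601 to 263 FPKM. Among the xenobiotic metabolism genes, 6 of 31 tested members rose and 11 fell (6 and 11 adjusted over the list alone, median log2 -0.44). Cyp2a22 fell from 16.6 to 0.180 FPKM (log2 -6.53), Cyp2b13 from 16.5 to 0.722 FPKM and Rgs16 from 49.7 to 1.13 FPKM (log2 -5.46). Among the liver tumour-associated genes, 10 of 25 tested members rose and 2 fell (12 and 3 adjusted over the list alone, median log2 0.75). The fetal growth factor gene Igf2 rose from 5.41 to 203 FPKM (log2 5.23), Ly6d from 2.86 to 158 FPKM (log2 5.79) and the tyrosine kinase receptor gene Ntrk2 from 0.0530 to 3.86 FPKM (log2 6.19), while Gpc3 fell from 12.7 to 5.78 FPKM, Fabp5 from 27.3 to 3.72 FPKM and Afp was at 5.65 and 6.63 FPKM and did not pass. Among the cell cycle genes, 2 of 35 tested members fell and none rose (0 and 0 adjusted over the list alone, median log2 -0.35). Mki67 was at 6.11 and 4.18 FPKM and did not pass. In this table the sign of the deposited test score was opposite to the fold change for all 14614 tested genes with both, whereas it was the same for every such gene in the other 3 tables. The directions given for 2 weeks therefore rest on the labels of the 2 value columns.

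In Pten livers after 1 week, most tested cell cycle genes rose, with 12 of 24 cholesterol synthesis and 11 of 23 fatty acid synthesis genes. Falls included 17 of 32 tested drug-metabolising genes and 10 of 18 immediate early genes. The kinase gene Plk1 rose from 2.29 to 5.83 FPKM, the lipogenic gene Thrsp from 592 to 2042 FPKM and the hepatic hormone gene Fgf21 from 2.15 to 20.1 FPKM (log2 3.22), while the metallothionein gene Mt1 fell from 1632 to 199 FPKM (log2 -3.04). Mir6236, annotated as a microRNA gene, and the mitochondrial tRNA synthetase gene Lars2, both chosen after their values were seen, fell in the same comparison. Mir6236 went from 22229 to 7155 FPKM (log2 -1.64) and Lars2 from 54.1 to 18.6 FPKM (log2 -1.54). Both also differed between the models without poly I:C. In the controls of 2 weeks Lars2 was at 575 FPKM in Shp2 and 28.3 FPKM in Pten livers, and Mir6236 at 281900 and 10889 FPKM. Whether poly I:C caused their falls was not tested. In all 1436 genes passed in the authors' deposited table, 715 up and 721 down. Of them 174 were below 1 FPKM in both groups.

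Among the cell cycle genes, 24 of 35 tested members rose and none fell (28 and 0 adjusted over the list alone, median log2 1.01). In the same comparison, among the erythroid genes, 6 of 11 tested members rose and 2 fell (8 and 2 adjusted over the list alone, median log2 1.22), with Slc4a1 rising from 0.279 to 1.66 FPKM and the transferrin receptor gene Tfrc falling (log2 -1.84). Mki67 rose from 3.20 to 5.73 FPKM (log2 0.84), with an implied error of at most 0.21, Cdk1 from 9.64 to 27.1 FPKM, Rrm2 from 6.85 to 18.3 FPKM and Ccne1 from 1.66 to 4.83 FPKM. Among the cholesterol synthesis genes, 12 of 24 tested members rose and none fell (19 and 0 adjusted over the list alone, median log2 0.93), including Sqle from 21.7 to 63.8 FPKM and Insig1 from 35.6 to 110.1 FPKM. Among the fatty acid synthesis genes, 11 of 23 tested members rose and none fell (13 and 1 adjusted over the list alone, median log2 0.85), including the acetyl-CoA carboxylase gene Acacb from 18.1 to 69.4 FPKM and the elongase gene Elovl6 from 21.3 to 89.7 FPKM. Among the fatty acid oxidation genes, 1 of 24 tested members rose and 4 fell (1 and 5 adjusted over the list alone, median log2 -0.31). Among the xenobiotic metabolism genes, 3 of 32 tested members rose and 17 fell (3 and 19 adjusted over the list alone, median log2 -0.75), including Cyp2c37 from 379 to 79.3 FPKM and Cyp2b10 from 7.04 to 1.01 FPKM. Among the bile acid genes, 2 of 18 tested members rose and 4 fell (2 and 6 adjusted over the list alone, median log2 -0.15), with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, falling from 31.0 to 5.90 FPKM. Among the insulin and growth factor pathway genes, 7 of 24 tested members fell and none rose (0 and 8 adjusted over the list alone, median log2 -0.37), including the gluconeogenic gene Pck1 from 1173 to 469 FPKM and Foxo1 from 5.43 to 2.99 FPKM. Among immediate early genes, 10 of 18 tested members fell and none rose (0 and 14 adjusted over the list alone, median log2 -0.74), including Fosb from 1.61 to 0.119 FPKM, Gadd45b from 12.7 to 3.14 FPKM and Fos from 5.10 to 1.39 FPKM.

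In Pten livers at 1 week, Cd274 rose from 0.471 to 1.07 FPKM (log2 1.19) and Cxcl9 from 2.10 to 7.78 FPKM (log2 1.89), while Cxcl10 (6.48 and 4.94 FPKM), Ccl5 (13.5 and 17.7 FPKM), Stat1 (19.4 and 18.8 FPKM) and Gzmb (1.58 and 1.87 FPKM) did not pass. Among interferon-gamma-induced GTPases and chemokines, 2 of 21 tested members rose and none fell (4 and 0 adjusted over the list alone, median log2 0.37). Type I interferon-stimulated genes went both ways: 4 of 38 tested members rose and 5 fell (5 and 6 adjusted over the list alone, median log2 -0.12). The 2'-5' oligoadenylate synthetase family gene Oasl1 rose from 7.92 to 15.3 FPKM, and Ifit1 fell from 3.33 to 1.84 FPKM (log2 -0.85) and Isg15 from 25.8 to 17.5 FPKM (log2 -0.56). In MHC class II presentation, 4 of 11 tested members rose and none fell (5 and 0 adjusted over the list alone, median log2 0.50), with Cd74 rising from 65.8 to 97.5 FPKM (log2 0.57). Among the Kupffer cell markers, 5 of 15 tested members rose and none fell (7 and 0 adjusted over the list alone, median log2 0.37). Among the monocyte-derived macrophage markers, 3 of 18 tested members rose and none fell (4 and 0 adjusted over the list alone, median log2 0.29), and among the neutrophil markers, 4 of 15 tested members rose and 2 fell (7 and 2 adjusted over the list alone, median log2 0.62). Among T cell markers, none of 13 tested members passed (0 and 0 adjusted over the list alone, median log2 0.07), and among B and plasma cell markers, 1 of 16 tested members rose and 4 fell (1 and 5 adjusted over the list alone, median log2 -0.44). Among sinusoidal endothelial markers, 4 of 18 tested members rose and none fell (7 and 0 adjusted over the list alone, median log2 0.36). Acute phase genes went both ways: 6 of 23 tested members rose and 4 fell (6 and 5 adjusted over the list alone, median log2 -0.15). Orm2 rose from 7.08 to 40.0 FPKM and Lcn2 fell from 54.5 to 37.9 FPKM (log2 -0.52). The largest falls were Sult2a6 (from 8.84 to 0.266 FPKM, log2 -5.05) and Igf2 (from 30.0 to 1.37 FPKM, log2 -4.45), and Igf2's imprinted neighbour H19 fell from 253 to 61.1 FPKM. The largest rises were Ckmt1 (from 0.755 to 7.62 FPKM, log2 3.33) and Ctse (from 0.104 to 1.02 FPKM, log2 3.29).

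In Pten livers after 2 weeks, most tested cell cycle genes rose and most tested immediate early genes fell, and genes whose liver expression depends on sex and growth hormone held the largest rise and fall. The female-biased transcription factor gene Cux2 rose from 0.621 to 12.5 FPKM (log2 4.33), and the male-biased Cyp4a12a fell from 64.9 to 1.05 FPKM (log2 -5.95). In all 858 genes passed in the authors' deposited table, 415 up and 443 down, 144 of them below 1 FPKM in both groups.

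Among growth hormone and sex-dependent liver genes, 12 of 30 tested members rose and 12 fell (13 and 14 adjusted over the list alone, median log2 -0.41). The 12 that rose were all female-biased and the 12 that fell all male-biased in the list. At 1 week, 8 of 24 tested members rose and 6 fell (8 and 7 adjusted over the list alone, median log2 0.40). There 6 male-biased and 2 female-biased members rose, and the 6 that fell were female-biased. Cyp3a16 fell from 26.1 to 7.76 FPKM and Cyp2b13 from 54.6 to 23.0 FPKM at 1 week, and Serpina1e rose from 23.1 to 119 FPKM. At 2 weeks Cyp2b13 rose from 3.19 to 61.8 FPKM and Cyp3a16 from 0.640 to 12.0 FPKM, and Slco1a1 fell from 30.1 to 2.22 FPKM and Serpina1e from 453 to 62.4 FPKM. Several of these belong to families of similar genes. Eif2s3y was at 25.5 and 28.1 FPKM and Xist at 0.0258 and 0.00438 FPKM in the control and poly I:C groups. Among the cell cycle genes, 23 of 35 tested members rose and none fell (29 and 0 adjusted over the list alone, median log2 1.20), including Ube2c from 3.39 to 11.8 FPKM, Plk1 from 1.20 to 3.96 FPKM and Mki67 from 1.66 to 3.88 FPKM (log2 1.22). Among immediate early genes, 11 of 18 tested members fell and none rose (0 and 14 adjusted over the list alone, median log2 -0.85), including Fos from 5.42 to 0.754 FPKM and Dusp1 from 81.0 to 14.1 FPKM. Among xenobiotic metabolism genes, 10 of 33 tested members rose and 1 fell (10 and 1 adjusted over the list alone, median log2 0.13), including the oestrogen sulfotransferase gene Sult1e1 from 0.288 to 5.57 FPKM. Among the insulin and growth factor pathway genes, 6 of 24 tested members fell and none rose (1 and 6 adjusted over the list alone, median log2 -0.05), and among the cholesterol synthesis genes, 1 of 24 tested members fell and none rose (0 and 1 adjusted over the list alone, median log2 -0.17).

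In Pten livers at 2 weeks, among interferon-gamma-induced GTPases and chemokines, none of 20 tested members passed (0 and 0 adjusted over the list alone, median log2 -0.06), and among MHC class II genes, none of 10 tested members passed (0 and 0 adjusted over the list alone, median log2 -0.05). Among the type I interferon-stimulated genes, 3 of 38 tested members fell and none rose (0 and 3 adjusted over the list alone, median log2 -0.21), with Irf7 falling from 52.9 to 31.1 FPKM (log2 -0.77). Cd274 was at 0.507 and 0.830 FPKM (log2 0.71, implied error 0.26, q = 0.0607 in the authors' deposited table) and did not pass. Cxcl9 (7.96 and 6.56 FPKM), Cxcl10 (6.86 and 5.23 FPKM), Stat1 (26.5 and 22.6 FPKM) and Ccl5 (9.66 and 6.39 FPKM) did not pass either. Among the Kupffer cell markers, 2 of 15 tested members fell and none rose (0 and 2 adjusted over the list alone, median log2 -0.29), and among the monocyte-derived macrophage markers, 1 of 20 tested members rose and 2 fell (1 and 4 adjusted over the list alone, median log2 -0.33). Among acute phase genes, 3 of 24 tested members rose and 5 fell (3 and 5 adjusted over the list alone, median log2 -0.01), with Saa2 falling from 56.7 to 21.9 FPKM (log2 -1.37). Other large falls were the hormone-responsive transcription factor gene Zbtb16 (from 8.87 to 0.843 FPKM) and the lipoxygenase gene Alox15 (from 1.09 to 0.0481 FPKM).

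**Figure D2:**
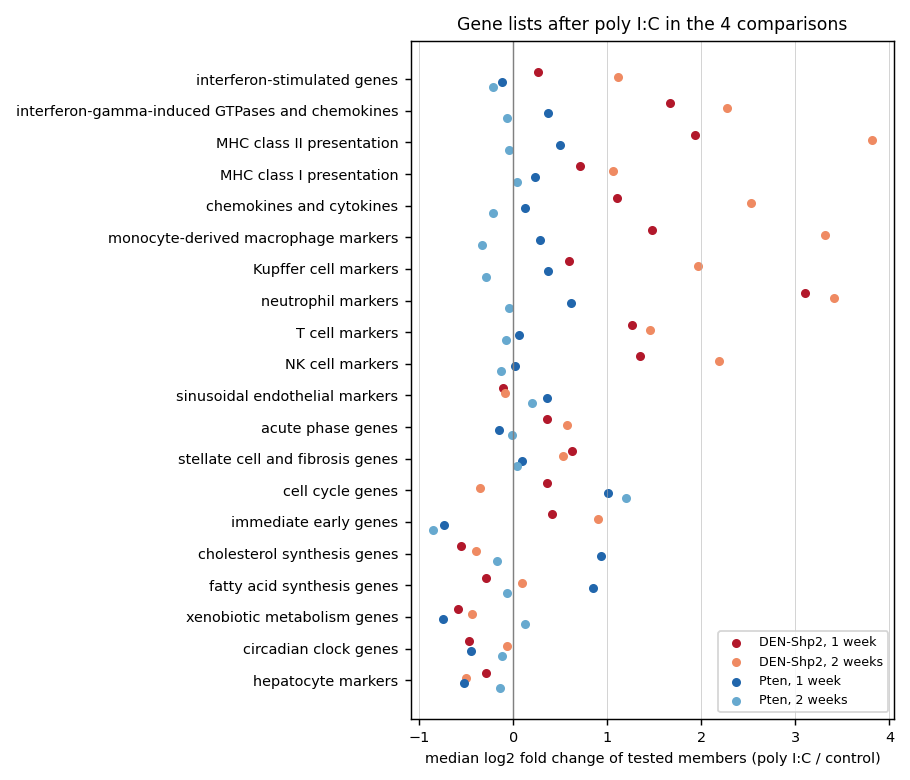
Median log2 fold change (poly I:C over control) of the tested members of 20 gene lists, 1 point for each of the 4 comparisons. The MHC class II median was 3.82 in Shp2 and -0.05 in Pten livers at 2 weeks, that of monocyte-derived macrophage markers 3.32 and -0.33, and cell cycle genes lie to the right in Pten livers (1.01 and 1.20).

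The next question was whether the effect differed with time. In Shp2 livers 598 genes rose and 142 fell at both times, where independent lists would share 74.2 and 12.3, and 19 went opposite ways, where 60.3 were expected. These values rest on the column labels of the table of 2 weeks. With its direction turned, 19 genes would share their direction and 740 would not. The difference test found 53 of 13679 genes, 50 when X and Y genes were left out. Sex chromosome transcripts differed between the groups at 1 week and not at 2 weeks, so time and sex are not separated here. Fabp5, on an autosome, was among the genes that differed, rising at 1 week and falling at 2 weeks (difference -3.82 with an implied error of 0.76 on the log2 scale, 1.94 if turned). Cd274 did not differ by this test (difference 1.13 with an implied error of 0.94), and neither did Saa2 (3.85 with an implied error of 1.95), whose errors are upper bounds; turned, the differences would be -5.27 and -10.48. Across genes, which are not independent replicates, the log2 fold changes of the 2 times had r = 0.54 and rho = 0.51, or -0.54 and -0.51 if turned. In Pten livers 146 genes rose and 106 fell at both times, against 18.1 and 18.5 for independent lists, and 92 went opposite ways, against 36.6. The difference test found 667 of 15194 genes, with r = 0.12 and rho = 0.08 across genes. Of the sex-dependent list, 9 members had a higher effect at 2 weeks and 9 a lower one. Of the cholesterol synthesis list, 10 of 24 members had a lower effect at 2 weeks and none a higher one, and of the cell cycle list 2 of 35 differed.

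The models were compared at each time. By the labels gene deletion and DEN differ together, so a difference is not one of the deleted gene alone. Mir6236 also stood far higher in the Shp2 libraries (281900 FPKM against 10889 FPKM in the controls of 2 weeks). How that bears on the comparison was not tested. At 2 weeks 1407 of 13655 genes differed, 956 with a lower effect in Pten livers. Stat1 (difference -2.18 with an implied error of 0.52), Cxcl10 (-3.66 with an implied error of 0.87) and Cd274 (-2.49 with an implied error of 0.83) had lower effects in Pten livers, and Mki67 a higher one (1.77 with an implied error of 0.37). Of the type I interferon-stimulated list 26 of 38 members had a lower effect in Pten livers, and of the cell cycle list 18 of 35 a higher one. At 1 week 514 of 13607 genes differed, 505 when X and Y genes were left out. The Shp2 groups of 1 week also differed in sex chromosome transcripts, so model and sex are not separated at that time. Stat1 (-1.59 with an implied error of 0.44) and Ifit1 (-1.67 with an implied error of 0.33) had lower effects in Pten livers, and the difference for Cd274 did not pass (-0.89 with an implied error of 0.59). Of the cholesterol synthesis list 15 of 24 members had a higher effect in Pten livers at 1 week. Genes called in both models shared their direction in 68.5% of 292 cases at 1 week and 36.8% of 239 at 2 weeks. All values at 2 weeks rest on the column labels of the Shp2 table, whose score has the opposite sign. With its direction turned, a run chosen after seeing the data, 1173 genes differed, 338 with a lower and 835 with a higher effect in Pten livers, and 63.2% of the shared calls had the same direction. The differences would be 1.71 for Stat1, 2.88 for Cxcl10, 3.91 for Cd274 and 0.68 for Mki67. Of the type I interferon-stimulated list 15 members would have a higher and 1 a lower effect in Pten livers, and of the cell cycle list 4 a higher one. The time comparison of Shp2 livers would then give 2132 genes in place of 53. The errors behind all these counts come from the deposited p-values, chosen after seeing the data. With errors from the deposited score, the planned source whose condition the data did not meet, the model difference counts fell to 76 at 1 week and 395 at 2 weeks, and those of time to 34 in Shp2 and 118 in Pten livers.

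**Figure D3:**
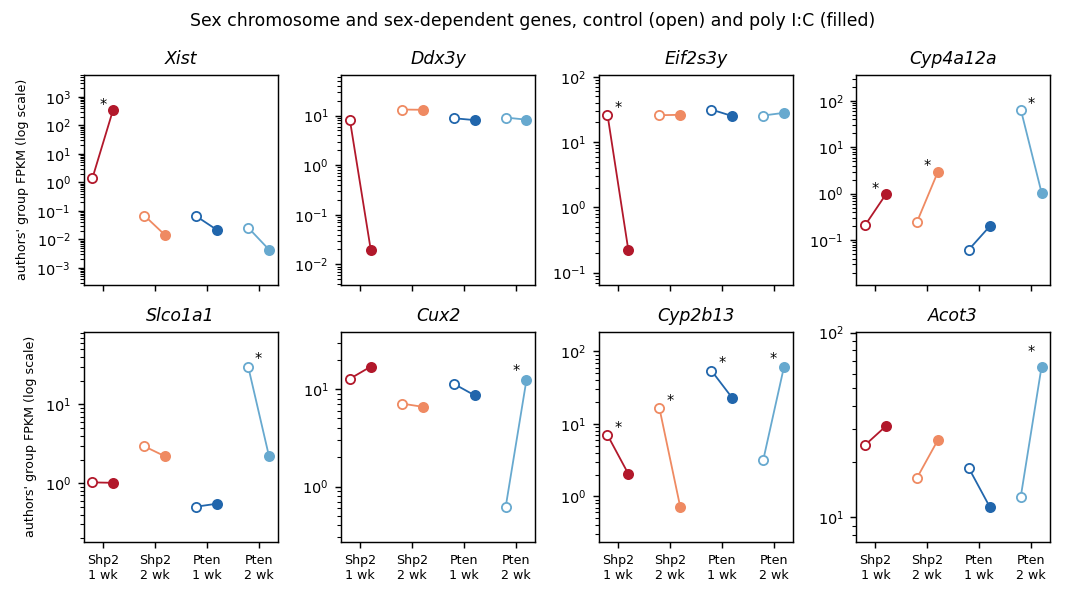
Authors' group FPKM (log scale) of 3 sex chromosome genes and 5 sex-dependent liver genes in the 4 comparisons, control as open and poly I:C as filled circles, with a star where the authors' deposited q was below 0.05. Xist was at 362 FPKM in the Shp2 poly I:C group of 1 week, and Cyp4a12a was at 64.9 FPKM in the Pten control group of 2 weeks.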

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

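The comparisons of times and models were planned, but the source of their errors was chosen after the data were seen, and so was every test of an explanation in this part. The poly I:C effect differed between times for 53 genes in Shp2 livers and 667 in Pten livers, and between models for 514 genes at 1 week and 1407 at 2 weeks, by the z test of the difference. Among the named genes, some were called in opposite directions with a difference that passed. Between times these were 5 in Shp2 livers, led by Fabp5 (difference -3.82 on the log2 scale, 2 weeks minus 1 week), Krt23 (-2.85) and A1bg (2.66), and 25 in Pten livers, led by Cyp3a16 (5.98), Cyp2b13 (5.53) and Serpina1e (-5.23). Between models these were 35 at 1 week, led by Cacna1b (-6.12, Pten minus Shp2), Mup3 (4.09) and Ces3a (4.01), and 35 at 2 weeks, led by Cyp4a12a (-9.51), Cyp2b13 (8.79) and Saa2 (-8.53). With the direction of the Shp2 table of 2 weeks turned, none of the 6 genes named for time in Shp2 or models at 2 weeks would be called in opposite directions in that comparison. Many other named genes then would be. They include Ubd (-12.03), Orm2 (-10.50) and Saa2 (-10.48) for time in Shp2. For models at 2 weeks they include Orm2 (7.44), Cd207 (5.94) and A1bg (3.07). The counts and leading genes of these 2 comparisons thus rest on the column labels. The differences of the 6 genes would be 1.94 (Fabp5), 0.52 (Krt23), 0.36 (A1bg), -2.39 (Cyp4a12a), -0.24 (Cyp2b13) and 5.79 (Saa2). Sex chromosome transcripts differed between the Shp2 groups of 1 week, so the differences that use that table are not assigned to time or model alone.

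Most tested members of the interferon-gamma-induced, MHC class II, monocyte-derived macrophage and neutrophil lists rose in Shp2 livers at both times. A lower share of hepatocytes alone would raise markers of every other cell type alike. The values of 1 week argue against it as the only cause. There the monocyte-derived macrophage list lay above the endothelial list by 1.58 at the median (log2), and the quartiles did not overlap. At 2 weeks the medians were 3.32 and -0.08 by the column labels, and their signs would reverse if turned. A lower share together with other changes stays open, since the hepatocyte list had medians of -0.29 and -0.50. The sex of the animals stays open at 1 week. Of the 59 members of these and the T cell, NK cell and cytotoxic lists called up then, 89.8% were also called up at 2 weeks, where Y transcripts were alike in both groups, against 69.9% of all genes called up at 1 week and tested at both times. With the direction of 2 weeks turned these shares would be 0% and 1.17%, so they rest on the column labels. Sex and treatment coincided at 1 week and cannot be told apart there. The opposite sign of the deposited score may mean that the group columns of 2 weeks were exchanged; 97.5% of genes called at both times went the same way, which argues for the column labels only if the effect is alike at both times.

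By the column labels, 4 of 24 tested members of the sex-dependent list rose and 8 fell in Shp2 livers at 2 weeks. The median log2 fold change there was -0.31. In Pten livers at 2 weeks 24 members changed, and the rest of this paragraph concerns those changes. The median log2 fold change of the 4 Y-linked genes was -0.00387 and Xist stayed at or below 0.0258 FPKM, which argues against animals of different sex. Reads shared between similar genes cannot account for the 6 called members outside large families, Cux2, Elovl3, C8b, A1bg, Prom1 and Abcd2, which all moved toward the female pattern; for the 18 called members of large families, which did too, sharing stays open. For 12 of 12 male-biased genes that fell, the Pten control group of 2 weeks had the highest value of all 8 groups, while 5 of 12 female-biased genes that rose had their lowest value there. Whether the groups of different tables were normalized together is not given in the sources used here. The Pten control group of 1 week stood at the other end for 5 of these male-biased genes, with their lowest value, and 3 of these female-biased genes, with their highest. So an unlike animal among the controls of 2 weeks and an effect of poly I:C cannot be told apart from group values.

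Some clock genes and some lipid synthesis genes changed in Pten livers at 1 week. Arntl and Nr1d1, which peak at opposite times of day, changed in opposite directions (difference -2.21 on the log2 scale). Another time of day or feeding state at collection is a candidate explanation, but an effect of poly I:C on the clock would give the same values, and collection times are not given in the sources used here. In Shp2 livers at 1 week Arntl rose and Nr1d1 fell, again in opposite directions, with a clock list median of -0.47. The same explanations cannot be told apart there either.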

How the results depend on the processing

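Counts of changed genes are given for Shp2 livers at 1 and 2 weeks and Pten livers at 1 and 2 weeks, in that order. Against 1233, 1853, 1436 and 858, a q below 0.01 left 676, 1245, 849 and 544, a change of 2-fold or more left 730, 1240, 652 and 394, and 2-fold with 0.1 or 1 FPKM added left 718, 1282, 590 and 361 or 413, 932, 307 and 166. These thresholds lower counts by construction. The 2-fold limit took the share of rises in Shp2 livers at 1 week from 71.1% to 81.9%, and with 1 FPKM added the share in Pten livers at 2 weeks went from 48.4% to 32.5%, and the cause was not tested. Adjusting over all genes of 1 table whatever their status gave 613, 1355, 975 and 553, which changes both the genes and the scope of the adjustment. Chosen after seeing the data, calls in the same direction at the other time numbered 740 in Shp2 (19 with the direction of the Shp2 table of 2 weeks turned) and 252 in Pten livers. Adjusting the tested genes within a table alone, also chosen then, gave 929, 1732, 1411 and 733. A 1 FPKM filter and adjusting over the 4 tables moved none of these 4 counts by over 1.5 times. Also chosen after seeing the data, leaving out X and Y genes gave 1197 in Shp2 livers at 1 week, and leaving out the sex-dependent and sex chromosome lists gave 1221 there and 834 in Pten livers at 2 weeks. These lists are short, so leaving them out could lower the counts only slightly by construction. Any other sex-dependent genes stay in. Centring turned the sign of no called gene, and calls rest on the deposited q, which it cannot move. Differences of the effect (time in Shp2, time in Pten, models at 1 and at 2 weeks) numbered 53, 667, 514 and 1407. They fell to 23, 368, 250 and 866 at an adjusted p below 0.01 and to 34, 118, 76 and 395 with the larger errors of the deposited score, the planned source whose condition was not met, run after seeing the data. With the direction of the Shp2 table of 2 weeks turned, also run then, they were 2132 for time in Shp2 and 1173 for models at 2 weeks. Of 99 list medians outside the central 95% of random lists, 2 came to lie inside that range with 1 FPKM added, 7 with members at 1 FPKM or more, and none with 0.1 FPKM added. Adding a constant cannot turn the sign of a fold change and centring cannot move the percentiles, both by construction. No paired analysis was possible because the tables used here hold only group values, and for the same reason leaving out replicates, a count-based alternative and other splits of the mice were not run. How many reads support each value is unknown, so what depth limits cannot be stated beyond the genes left untested.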

Other observations

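Some biology lay outside the comparisons above. For the clock genes of both models, another time of day or feeding state at collection stays open, as stated above. Among clock genes at 1 week in Shp2 livers, 1 of 18 tested members rose and 4 fell (2 and 7 adjusted over the list alone, median log2 -0.47), with Arntl rising from 0.418 to 1.35 FPKM and Nr1d1 falling from 31.7 to 14.5 FPKM. At 1 week in Pten livers, 1 of 19 tested members rose and 9 fell (2 and 9 adjusted over the list alone, median log2 -0.45), with Arntl falling from 2.73 to 1.76 FPKM, Nr1d1 rising from 15.9 to 47.5 FPKM and Per1 falling from 32.2 to 11.9 FPKM. The 4 globin genes listed fell in Shp2 livers at both times and rose in Pten livers at 1 week. Of the red cell list in Shp2 livers, 4 of 9 tested members fell and none rose (1 and 4 adjusted over the list alone, median log2 -0.80) at 1 week, and 4 of 10 tested members fell and none rose (0 and 5 adjusted over the list alone, median log2 -0.69) at 2 weeks. How reads were shared among the globin copies is not given in the sources used here. Hbb-bs went from 1767 to 403 FPKM in Shp2 and from 751 to 1364 FPKM in Pten livers at 1 week. Among immediate early genes in Shp2 livers at 2 weeks, 8 of 17 tested members rose and 2 fell (9 and 3 adjusted over the list alone, median log2 0.90), with Jun rising from 3.69 to 13.4 FPKM there and falling from 19.5 to 5.84 FPKM in Pten livers of the same time. Among p53 target genes, the cell cycle inhibitor gene Cdkn1a rose in Shp2 livers at 2 weeks (from 17.5 to 30.3 FPKM) and fell in Pten livers at 2 weeks (from 29.0 to 11.0 FPKM). Of that list in Shp2 livers 6 of 19 tested members rose and none fell (8 and 0 adjusted over the list alone, median log2 0.43), and in Pten livers 1 of 20 tested members rose and 4 fell (1 and 4 adjusted over the list alone, median log2 -0.01). All directions for Shp2 livers at 2 weeks in this part rest on the column labels. If turned, Jun and Cdkn1a would fall in both models. Their differences (Pten minus Shp2) would be 0.12 and -0.61 in place of -3.60 and -2.18.

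Further lists were read in Shp2 livers at 2 weeks. Among antioxidant genes, 6 of 18 tested members rose and 1 fell (6 and 1 adjusted over the list alone, median log2 0.52), with the haem oxygenase gene Hmox1 rising from 15.8 to 72.1 FPKM. Among glycolysis and hypoxia genes, 7 of 20 tested members rose and none fell (7 and 0 adjusted over the list alone, median log2 0.24), and among heat shock and ER stress genes, 1 of 19 tested members rose and 4 fell (1 and 5 adjusted over the list alone, median log2 -0.29). Among cholangiocyte markers there, 3 of 13 tested members rose and 2 fell (3 and 4 adjusted over the list alone, median log2 -0.63). Ribosomal protein genes gave 1 call in the 4 tables, with a median log2 fold change of -0.21 in Shp2 livers at 2 weeks. Genes of neighbouring organs gave 1 call at 1 week in Shp2 livers and 1 at 1 week in Pten livers.

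A few values were chosen after they were seen. The pituitary hormone gene Gh fell in 3 tables, from 13.9 to 5.40 FPKM and from 8.29 to 1.48 FPKM at 1 week in Shp2 and Pten livers and from 10.3 to 2.68 FPKM at 2 weeks in Pten livers, and rose in Shp2 livers at 2 weeks from a control listed at 0 to 1.22 FPKM. Mir6236, annotated as a microRNA gene, held 958861 and 1358040 FPKM in the control and poly I:C groups of Shp2 livers at 1 week, 281900 and 199741 at 2 weeks. In Pten livers at 2 weeks it was at 10889 and 13438 FPKM, and its fall at 1 week had q = 0.00128 in the authors' deposited table. All genes together summed to 2913440 and 3784910 FPKM in the control and poly I:C groups of Shp2 livers at 1 week. At 2 weeks the sums were 2043980 and 1911720. In Pten livers they were 842823 and 737296 at 1 week, and 789861 and 726371 at 2 weeks. The share held by Mir6236 thus differed between the models, and the cause was not tested. Xist was at 1.41 FPKM in the Shp2 control group of 1 week and at 0.0686 FPKM in that of 2 weeks. Y-linked Ddx3y went from 8.02 to 0.0199 FPKM in Shp2 livers at 1 week, yet its q in the authors' deposited table was 0.258.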
